A study of Gallus gallus with 4 samples.

How the data were processed

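The study measured RNA in neural crest cells of chick embryos, the migratory cells that leave the dorsal neural tube and form much of the face, the peripheral nervous system and the pigment cells. Embryos received by electroporation an enhancer of the FoxD3 gene, NC1 for the head or NC2 for the trunk, and were grown to the stage of interest. Head or trunk was then dissected and dissociated, and living GFP-positive cells were sorted by flow cytometry, per the labels' protocols. The labels give 4 libraries in 2 groups: 2 of cranial neural crest (replicates A and B) at Hamburger-Hamilton stage HH9+ and 2 of trunk neural crest (replicates A and C) at stage HH14. Axial level, stage and enhancer change together between the groups, so the comparison cannot separate them. The RNA was amplified as cDNA with a kit for small inputs and sequenced as single reads, per the labels' protocols.

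TopHat, Cufflinks and Cuffdiff 2.1 and the chicken assembly galGal4 are named in the submitters' processing notes, which give no order or role. The deposited table holds the authors' own comparison and no values per library, so replicate spread, read depth and library totals are unknown here and no SD, n or counting interval is given. The deposited table gives 1 cranial and 1 trunk value per row, read as FPKM (fragment abundance scaled for transcript length and sequencing depth) because Cuffdiff writes that unit, although the file headers call the columns only values. The log2 fold in the authors' table is trunk over cranial. It equalled the ratio of both values within 0.0001 in all 212 rows, and is turned round here so that a positive log2 value means higher in cranial cells. The authors' deposited table also holds a test score, a p-value and an adjusted q-value per row. The score was positive where the cranial value was higher, and in the 193 rows with a p of at least 1e-10 the p lay within 1% of the two-sided normal p of that score. An implied standard error (SE) of the log2 fold was therefore taken as the log2 fold divided by the score. This reading was chosen after the values were seen. It holds only if the score is a log fold over its own error, which the file headers do not state, and it comes from the authors' error model. No row was higher in trunk, and every row was marked as significant by the authors, with a largest q of 0.0485. The table is a selected list, and genes outside it have no value here. No replicate test was possible from 1 value per group.

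Coordinates are given as the authors' table writes them. The processing notes name galGal4, but 8 rows lie on sequences called chrUn_random, chr22_random or chrE22C19W28_E50C23, which are names of the earlier assembly galGal3, so the build of the coordinates is not settled. A row's interval is the locus that the authors' software analysed, and 10 rows share a locus with another row (5 loci). No exon, intron or UTR position was assigned. Gene names were taken from the table. Of 212 rows, 110 carried a symbol, or a protein entry name beginning with a symbol, of the chicken gene table of assembly GRCg7b, 3 a gene number that led to a symbol, 1 a symbol outside that gene table, and 25 an older symbol or a protein entry name translated by hand (26 translations, such as CADH1 to CDH1, were written after the names were seen). The other 73 rows, 52 of them under a protein accession, were left without a symbol, and no Ensembl identifier could be matched to the gene table.

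Before the data were examined, 20 gene lists with 622 entries were fixed: neural crest regulators, cranial regulators known from this study, anterior and posterior patterning, epithelial-mesenchymal transition and adhesion, extracellular matrix, chondrogenic and facial mesenchyme, neuronal, glial and pigment derivatives, axon guidance, WNT, BMP and TGF-beta, FGF and receptor tyrosine kinase, Notch, and retinoic acid and hedgehog signalling, cell cycle, and 5 lists of markers of other cell types. Family entries took family members only, so that BMP2K and HESX1 did not count as BMP or HES genes, a limit set after the names were seen. List members were counted with symbols as listed and again with translated names. No enrichment was tested, because the genes that could have entered the table are not known. The named genes were also set by a rule fixed before the data were examined: the 15 rows with the largest fold among those with a symbol and at least 1 FPKM in the cranial group, the 5 highest cranial values, up to 6 members per list with the largest fold, and FOXD3, SOX10, HOX genes and the study's 6 cranial regulators where present. Exceptions are stated where they occur. The designs for counts or FPKM per library that were written beforehand were not used.

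For the extracellular matrix list, which had the most listed rows, the median log2 fold was placed among 10000 random lists of the same size. Each member was drawn from the 20 rows nearest in level, the member itself included. The design written beforehand did not hold this placing. The methods that follow were chosen after the data were seen. The number of tests behind the q-values was found by trying every number from 5000 to 60000 and asking whether number times p over q was a whole rank within 0.01. A multiple of the true number gives whole ranks too, so the smallest number that did nearly as well as the best was taken. On simulated comparisons with as many listed rows this recovered the number of tests in 4 of 4 cases. That search covered a narrower range, which for some simulated numbers held no multiple of the number, so the choice between multiples was tried only in part. Neighbouring listed genes were counted in the order of 18023 protein-coding genes of the gene table and compared with 10000 random draws with as many genes per chromosome. In simulated genomes of 15000 genes, 1 of 40 random sets reached a p under 0.05, and with 10 planted pairs 10 were found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were minimum FPKM values, a stricter q, fold limits, pseudocounts, translated names and removal of rows sharing a locus.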

Results

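RNA sequencing compared sorted neural crest cells from the head of chick embryos at stage HH9+ with those from the trunk at stage HH14, to find genes characteristic of the cranial crest as it delaminates. There were 2 libraries per group, and the labels do not say whether they came from separate pools of embryos. The authors' deposited table holds 212 rows, each with 1 FPKM value per group, and all 212 were higher in cranial cells. Depth per library is unknown, and the genome build of the table's coordinates is not settled (galGal4 per the submitters' processing notes, sequence names of galGal3). The p-values behind the table come from the authors' own test. How that test used the 2 libraries per group is not stated, and no replicate check could be made.

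The transcripts higher in cranial cells included the transcription factor genes LHX5 and SOX8, the Nodal co-receptor gene CFC1, the guidance gene DRAXIN and the cadherin gene CDH1. LHX5, a LIM homeobox transcription factor of the anterior neural plate, was listed at 3.34 FPKM in cranial and 0.153 FPKM in trunk cells in the authors' deposited table, a 21.8-fold difference (log2 4.44, implied SE 0.90, q = 0.000120). This value is uncertain, because the LHX5 row shares its locus with an unnamed row listed at 70.5 FPKM in the authors' deposited table. SOX8, a SoxE transcription factor expressed in neural crest, stood at 30.7 against 3.30 FPKM in the authors' deposited table, 9.31-fold higher in cranial cells (log2 3.22, implied SE 0.68, q = 0.000288). CFC1, a co-receptor for Nodal ligands, was 20.8-fold higher in cranial cells in the authors' deposited table, at 28.3 against 1.36 FPKM (q = 6.73e-07). Draxin, a secreted guidance protein and WNT antagonist, reached 107 FPKM in cranial against 9.08 FPKM in trunk cells in the authors' deposited table, an 11.8-fold difference (q = 3.92e-07). CDH1, the epithelial cell adhesion molecule E-cadherin, was 4.40-fold higher in cranial cells in the authors' deposited table, at 24.9 against 5.65 FPKM (q = 0.00283).

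**Figure D1:**
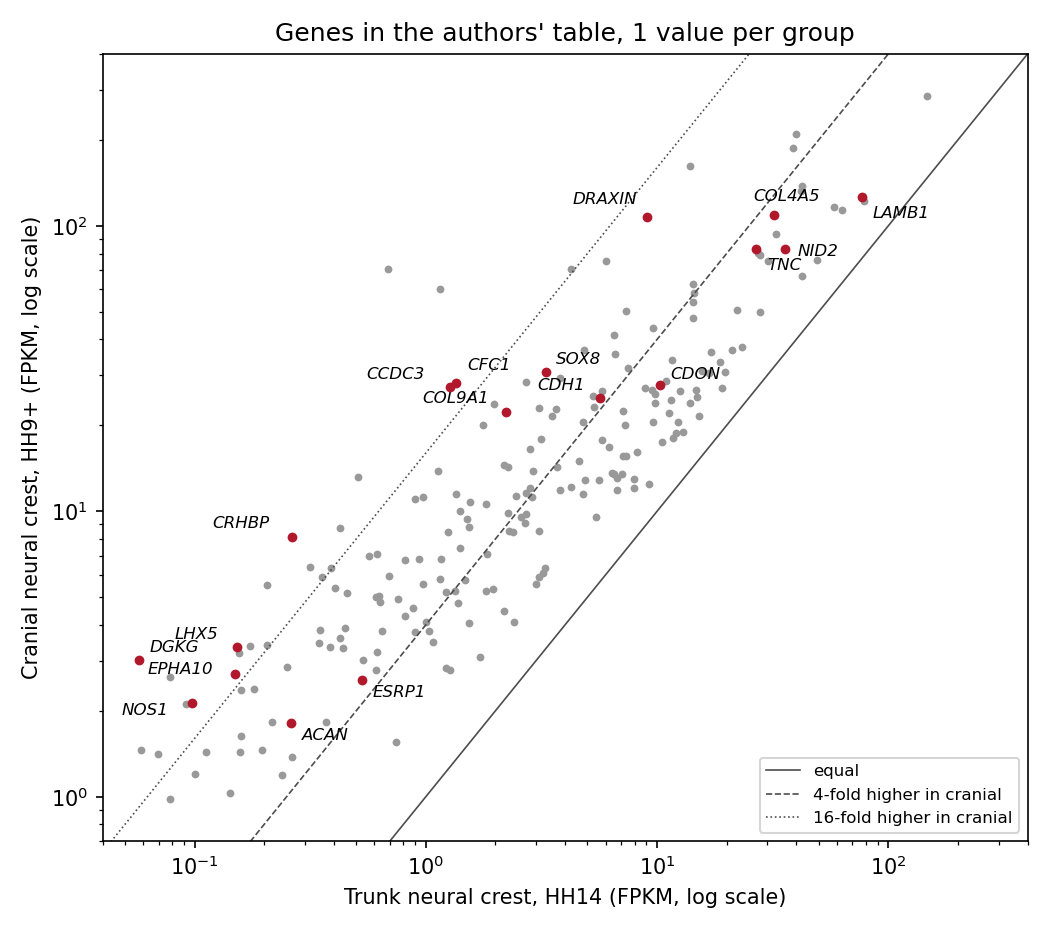
Each point is 1 row of the authors' table, with its trunk FPKM on the horizontal and its cranial FPKM on the vertical axis, both on log scales. All 212 points lie above the line of equal levels, 115 of them by at least 4-fold (dashed line) and 23 by at least 16-fold (dotted line). Some genes of the text are in red with their symbols, and its other genes are grey like the remaining rows.

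Differences across the table ranged from 1.35-fold to 103-fold, with a median of 4.34-fold (log2 2.12) in the authors' deposited table. At least 2-fold differences were found in 173 rows of the authors' deposited table, at least 8-fold in 57 and at least 16-fold in 23. A q under 0.001 was given for 82 rows of the authors' deposited table and 3 rows were listed with a q of 0. Levels covered a wide range, with cranial values from 0.983 to 286 FPKM (median 12.1) and trunk values from 0.0577 to 147 FPKM (median 2.72) in the authors' deposited table. Trunk values under 1 FPKM were given for 63 rows of the authors' deposited table, where a fold rests on a small denominator. With 1 FPKM added to both values of the authors' deposited table, the log2 fold of LHX5 was 1.91 in place of 4.44. The implied SE of the log2 fold had a median of 0.51 and ran from 0.10 to 1.64 over the authors' deposited table.

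The 15 genes with a symbol and the largest fold all had trunk levels of at most 1.36 FPKM in the authors' deposited table. DGKG, a diacylglycerol kinase, had the largest fold of them as deposited, at 3.01 against 0.0577 FPKM in the authors' deposited table, with a wide implied SE (log2 5.70, implied SE 1.64, q = 0.0226). The order changed with 1 FPKM added to both values of the authors' deposited table, where CCDC3 (log2 3.64) and CFC1 (log2 3.63) stood highest of the 15, DGKG stood at 1.92 and the lowest, PHF24, at 1.18. ADPRHL1, related to ADP-ribosylhydrolases, was listed at 33.8-fold with similar uncertainty in the authors' deposited table (log2 5.08, implied SE 1.55, q = 0.0388). The corticotropin-releasing hormone binding protein CRHBP was 30.9-fold higher at 8.15 FPKM (q = 6.56e-07), and the neuronal nitric oxide synthase NOS1 was 21.8-fold higher at 2.14 FPKM (q = 3.43e-09), both in the authors' deposited table. The NOS1 row shares its locus, chromosome 15 from 11517414 to 11634995, with a row for KSR2, named for that overlap after its value was seen, which was 12.5-fold higher at 0.983 FPKM in the authors' deposited table (q = 0.0482), so the values of both are uncertain. CCDC3, encoding a secreted coiled-coil protein, stood at 27.2 FPKM and 21.4-fold (q = 1.48e-09), and the secreted protease ADAMTS15 at 8.75 FPKM and 20.6-fold (q = 1.61e-11), in the authors' deposited table. PNOC, the precursor of the neuropeptide nociceptin, was 16.6-fold higher at 5.90 FPKM (q = 8.47e-05) and the postsynaptic protein gene ELFN2 16.5-fold higher at 3.39 FPKM (q = 4.04e-05) in the authors' deposited table. The unconventional myosin MYO1H, the synaptonemal complex gene SYCP1, PHF24 (listed as KIAA1045) and C1orf88 were listed between 20.3-fold and 24.9-fold, with q from 0.00497 to 0.0339 in the authors' deposited table. Cranial levels of these 4 genes lay between 1.42 and 6.40 FPKM in the authors' deposited table.

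The fixed lists of crest regulators and of patterning genes had between 0 and 2 listed rows each, with translated names. The list of neural crest regulators had 1 listed row among its 32 entries, SOX8, which lies on chromosome 14 from 5768067 to 5773293 in the authors' deposited table. Of the 6 cranial regulators known from this study, LHX5 and SOX8 were present by symbol, and this list was chosen by the study on these samples and is not independent evidence of direction. POU4F3, DMBX1, TFAP2B and ETS1 did not appear under those symbols, nor did FOXD3 or SOX10, while 73 rows carry no symbol and were not searched. The anterior neural patterning list had 2 listed rows among its 33 entries with translated names, LHX5 and a combined row for the homeobox gene HESX1 and its neighbour IL17RD, an inhibitor of FGF signalling. That combined row was 1.78-fold higher in cranial cells in the authors' deposited table, at 33.4 against 18.8 FPKM, and its reads cannot be divided between the genes (q = 0.0389). Posterior patterning genes, HOX genes included, had 0 listed rows under their symbols. The table holds no gene higher in the trunk, so this count says nothing of such genes there.

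The extracellular matrix list, the longest with 47 entries, had 5 listed rows by symbol and 8 with translated names. Cartilage matrix genes had the 2 largest differences of the list in the authors' deposited table, without a pseudocount, with COL9A1, a chain of cartilage collagen IX, 10.04-fold higher at 22.3 FPKM (q = 0.000222) and the proteoglycan aggrecan, ACAN, 6.92-fold higher at 1.82 FPKM (q = 0.000460). With 1 FPKM added to both values of the authors' deposited table, the log2 fold of ACAN was 1.16 in place of 2.79, below those of COL4A5 (1.73), TNC (1.59) and COL27A1 (1.23). Both are also the 2 listed members of the chondrogenic and facial mesenchyme list of 43 entries. COL4A5, a chain of basement membrane collagen IV, stood at 109 FPKM in cranial against 32.1 FPKM in trunk cells in the authors' deposited table, a 3.39-fold difference (log2 1.76, implied SE 0.44, q = 0.00462). COL4A6, which lies beside it on chromosome 4, was 2.74-fold higher at 5.35 FPKM (q = 0.00840) in the authors' deposited table. Tenascin-C, TNC, a matrix glycoprotein of migration routes, was 3.08-fold higher at 83.0 FPKM (q = 0.0351), and the fibrillar collagen COL27A1 2.78-fold higher at 8.55 FPKM (q = 0.000458), in the authors' deposited table. The 2 members with the smallest differences, named outside the rule, were nidogen-2 (NID2) at 2.32-fold and laminin beta 1 (LAMB1) at 1.63-fold in the authors' deposited table, with cranial levels of 82.7 and 126 FPKM. The median log2 fold of the 8 matrix rows was 1.55, at the 17.9th percentile of 10000 random lists of listed rows matched on level. The draws could include the matrix rows themselves, and 8 rows are few. A difference from other rows of the table was therefore not shown and is not excluded.

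**Figure D2:**
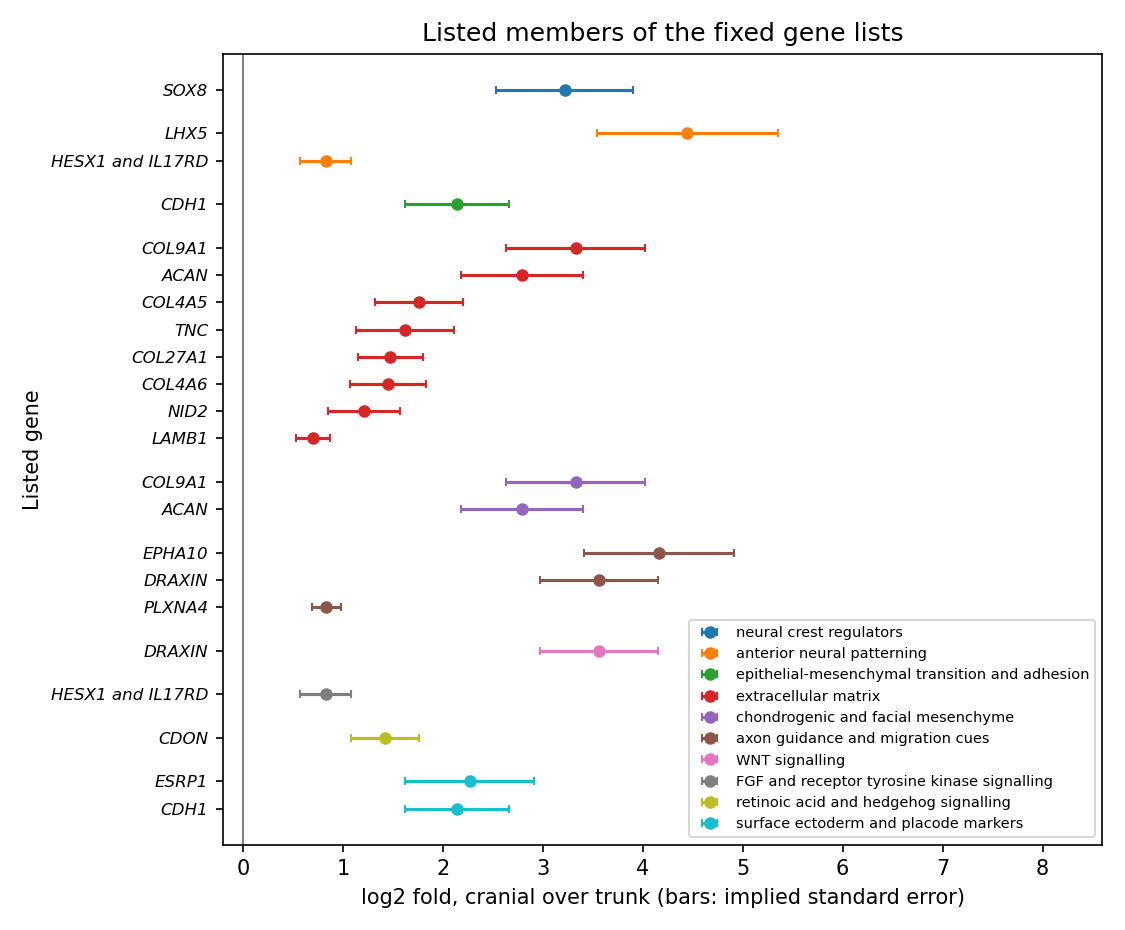
Points give the log2 fold of cranial over trunk (horizontal axis) for each listed member of the fixed gene lists, with translated names and the implied standard error as bars. Colours mark the lists, a gene in several lists is drawn in each except that of the study's cranial regulators, and the differences run from 0.70 for LAMB1 to 4.44 for LHX5.

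Genes of guidance and signalling formed small groups. The axon guidance list had 3 listed rows with translated names, the ephrin receptor EPHA10 at 17.9-fold and 2.68 FPKM (q = 6.39e-06), draxin, and the semaphorin receptor component PLXNA4 at 1.78-fold and 11.9 FPKM (q = 1.88e-06) in the authors' deposited table. With 1 FPKM added to both values of the authors' deposited table, the log2 fold of EPHA10 was 1.68 in place of 4.16. Draxin was the 1 listed member of the WNT list, and the row combining HESX1 and IL17RD the 1 listed row of the FGF and receptor tyrosine kinase list. CDON, a co-receptor for hedgehog, was the 1 listed member of the retinoic acid and hedgehog list, at 27.7 against 10.3 FPKM and 2.68-fold in the authors' deposited table (q = 0.00269). The lists for BMP and TGF-beta signalling, Notch signalling, the cell cycle, and neuronal, glial and pigment derivatives had 0 listed rows under their symbols.

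Markers of other cell types were sought among the listed rows, since a sort for GFP can carry other cells. The surface ectoderm and placode list had 2 listed rows among its 35 entries with translated names and 0 without, CDH1 and the epithelial splicing regulator ESRP1 (listed as RBM35A), the latter at 2.56 against 0.532 FPKM and 4.82-fold in the authors' deposited table (q = 0.0213). The log2 fold of ESRP1 was 1.22 in place of 2.27 with 1 FPKM added to both values of the authors' deposited table. CDH1 was also the 1 listed member of the list for epithelial-mesenchymal transition and adhesion. The lists of neural tube, paraxial and lateral mesoderm, endothelial and blood, and endoderm and notochord markers had 0 listed rows under their symbols. The 73 rows without a symbol were not searched, so such markers can be among them. A row outside the table has no value here, so these counts do not show that such markers were equal between the groups.

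The rows with the highest cranial level carried no symbol. A row listed by protein accession was highest at 286 FPKM and 1.95-fold, followed by ENSGALG00000022534 at 209 FPKM and 5.24-fold, in the authors' deposited table. The table does not pair them with gene names, and the other 3 of the 5 highest rows lay between 138 and 187 FPKM in the authors' deposited table. Among rows with a symbol, the highest cranial levels, chosen after the values were seen, belonged to LAMB1, the mitochondrial ribosomal protein gene MRPL13 at 116 FPKM, SSBP3 at 114 FPKM, COL4A5 and draxin, in the authors' deposited table. MRPL13 and SSBP3 differed by 1.998-fold and 1.81-fold between the groups in the authors' deposited table (q = 0.0240 and q = 0.0380).

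Listed rows lay on 31 chromosomes or other sequences, with 31 rows on chromosome 1, 19 each on chromosomes 2 and 3 and 17 on chromosome 4. These counts were not set against the number of genes per chromosome, so they show no concentration of listed rows. A Fisher exact test per chromosome, written beforehand for the case that all gene positions were given, was not run. Chromosome 15 held 9 rows, among them the largest difference of all, 103-fold for ENSGALG00000023187 at 70.5 against 0.686 FPKM in the authors' deposited table (log2 6.68, implied SE 0.90). That row has the same locus as LHX5, from 12878730 to 12889471. SDSL, a serine dehydratase-like gene named after its value was seen, begins at 12890123. SDSL was 9.997-fold higher in cranial cells in the authors' deposited table, at 3.47 against 0.347 FPKM (q = 0.00312), a fold that rests on a small denominator. Reads of overlapping genes cannot be assigned to 1 row with certainty, so the LHX5 value and that of the row at its locus are uncertain.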

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

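No alternative could change a direction, as every row of the table is higher in cranial cells. The count of 212 rows fell to 119 with at least 10 FPKM in the cranial group, to 134 at a q under 0.01, to 115 at 4-fold or more and to 57 at 8-fold or more, by construction. It stayed within 1.5 times under the other limits, including 202 rows without shared loci, an alternative chosen after seeing the data. The median log2 fold of 2.12 (95% order-statistic interval 1.92 to 2.37 over rows) became 1.51 with a pseudocount of 1 FPKM, 0.84 with 5 FPKM, and 1.63 over the 149 rows above 1 FPKM in both groups. That interval treats the selected rows as independent draws and holds no error between libraries. With a pseudocount of 1, the log2 fold of 17 of the 36 named rows moved by over 1 implied SE, all towards 0, LHX5 to 1.91 and DGKG to 1.92. Rows in any fixed list numbered 10 by symbol, 3 of them at least 4-fold, and 17 with translated names. No paired analysis was possible because the table holds 1 value per group, and the groups share only replicate letter A. Leaving out libraries, other normalizations and filters on counts were not run for the same reason. Depth is unknown, so its limit on low rows cannot be given.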

Other observations

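The rank calculation and the tests of neighbouring and of surface ectoderm genes in this part were chosen after the result was seen. The genes in this paragraph lie outside the fixed lists and were picked by known function after their values were seen, with no test of whether such genes are over-represented. The fixed lists of neuronal, glial and pigment derivatives (42 entries) and of neural tube markers (25 entries) had 0 listed rows under their symbols. Low levels set several of these folds, so the fold with 1 FPKM added to both values is given beside those that moved by over 1.5 times. In the authors' deposited table, the metabotropic glutamate receptor GRM4 was 4.58-fold higher in cranial cells at 26.4 FPKM, and GRM3 10.2-fold at 1.63 FPKM (2.27-fold with 1 FPKM added). The calmodulin-dependent kinase CAMK1G was 11.4-fold higher at 5.18 FPKM in the authors' deposited table (4.25-fold with 1 FPKM added), and the calcium-stimulated adenylyl cyclase ADCY8 4.25-fold at 11.6 FPKM. The calcium channel genes CACNA1E and CACNA1H were 4.97-fold higher at 1.83 FPKM (2.07-fold with 1 FPKM added) and 2.31-fold at 2.82 FPKM in the authors' deposited table. CAMK4, a related kinase, was listed at 5.83-fold in the authors' deposited table, but it shares its locus with an unnamed row at 12.3-fold and its value is uncertain. CHAT, the enzyme that makes acetylcholine, was 5.23-fold higher at 3.21 FPKM (2.61-fold with 1 FPKM added) and the nicotinic receptor subunit CHRNA4 2.87-fold at 5.25 FPKM in the authors' deposited table. OPRL1, the receptor for the nociceptin made from PNOC, was 9.07-fold higher at 1.43 FPKM (2.099-fold with 1 FPKM added), and STMN4, a tubulin-binding protein, 14.9-fold at 2.36 FPKM (2.903-fold with 1 FPKM added), in the authors' deposited table. ASTN1 and BRINP2 were listed at 6.30-fold and 13.2-fold in the authors' deposited table (2.87-fold for BRINP2 with 1 FPKM added), with uncertain values because their rows share a locus.

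The q-values carry information on rows outside the table. If q is the Benjamini-Hochberg adjustment, number of tests times p over q gives each row's rank among all tests. With 26269 tests, 175 of the 209 rows with a p above 0 (83.7%) had a whole rank, 97 of them odd. The number 52538, which is 2 times 26269, gave whole ranks in 177 rows, as a multiple must, but only 2 of these were odd. The smaller number was taken because it did nearly as well, and the few odd ranks at the larger go with that choice. Apart from both and the numbers close to them, the best number, 17513, gave 29.7%. On that choice, the listed row with the largest p, 0.00146, had rank 790, which leaves 578 tests at or below that p outside the table. What these tests were is unknown here, since 26269 exceeds the 18023 protein-coding genes of the gene table. They can be higher in trunk, features other than genes, tests of another comparison or left out for another reason. The table held 54 of the first 200 ranks, 56 of the next 200, 57 of the next 200 and 45 of the last 190.

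Of 136 listed genes placed in gene order, 6 pairs were direct neighbours (KSR2 with NOS1, LHX5 with SDSL, AGTRAP with DRAXIN, LRRN2 with NFASC, COL4A5 with COL4A6, BRINP2 with ASTN1), against a mean of 1.15 in 10000 random draws with as many genes per chromosome (one-sided permutation p = 0.001). A candidate explanation is reads of overlapping or closely spaced genes, as 2 of the pairs share a locus. With pairs sharing a locus, or under 10 kb apart in the authors' table or the gene table, left out of the data and the draws alike, 1 pair (LRRN2 with NFASC) was left against a mean of 0.303 (one-sided permutation p = 0.264), too few to decide, because 72.2% of all neighbouring gene pairs are that close. A first form of this test left out close pairs of the listed genes by the table's distances and not those of the draws, gave 2 pairs against a mean of 1.15 (one-sided permutation p = 0.319), and was read in favour of that explanation; the test and the rule for reading it were both changed after that result was seen. A regional difference in expression between the axial levels stays open and untested, and the draws used all protein-coding genes, not those expressed in these cells.

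The presence of CDH1 (24.9 FPKM) and ESRP1 (2.56 FPKM) in the authors' deposited table may reflect surface ectoderm cells in the cranial sort. It may also reflect expression in cranial crest itself, and the purity of the sort is unknown here. CDH1 is also in the adhesion list. Their log2 folds differed by 0.13 (implied SE 0.83), which decides nothing, because the fold that other cells would add depends on each gene's own level in the crest and the error is wide. Of 4 further genes known from epithelia, picked after their values were seen, the log2 folds in the authors' deposited table were 1.97 for ESRP2, 2.13 for SPINT1, 2.92 for SCNN1B and 3.08 for GJB1 (1.59 and 2.40 with 1 FPKM added), and genes picked from a table of cranial-enriched rows cannot decide it either. Stage, axial level and enhancer differ together between the groups and remain untested.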
